A study of Homo sapiens with 31 samples.

How the data were processed

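Total RNA of MCF10A cells was measured on 31 arrays of Illumina Ref8 BeadChips, 1 per sample: 7 Control, 6 Survivors, 3 Reset, 3 Repeat, and 2 each of IKB_control, IKB_survivors, IETD_control, IETD_survivors, zVAD_control and zVAD_survivors. Per the labels, 3 biological experiments on different days contributed 7, 8 and 16 arrays, with 1 to 2 replicates of a sample per experiment (3 for Control in experiment 1). Groups, replicate numbers and experiments were taken from the sample titles. The source texts of Survivors replicates 5 and 6 name Reset and Repeat treatment, in conflict with their titles and with the group sizes stated for the series; both were kept as Survivors, and every count was repeated without them. The labels do not state whether arrays were paired. Deviations from group means had a median r across genes of -0.03 (-0.51 to 0.46) over 13 parental pairs with the same number and experiment. Paired by order within experiment, 16 parental pairs had a median of -0.03 (-0.24 to 0.45), with all pairs of Control and Survivors between 0.09 and 0.45, so pairing was left open. The chip of each sample is not in the files used here.

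The deposited non-normalized table holds, per the file headers, an intensity per probe and array, on a linear scale without background subtraction or scaling between arrays. Beside each signal the deposited table gives a detection p-value, the measured share of negative control beads brighter than the probe. The authors also deposited a normalized table in log2 units with the same median (7.3) on every array. Per the submitters' processing notes lumi was used, without a version; the transform, the normalization and the scanner software are not given in the sources used here. In that table the scale (log2, with a raised floor) and direction were checked against the signals of each array, and what set its floor remains unknown. A second normalized table has 31 value columns whose headers match no label; these were not used, and only its probe identifiers, bead addresses and symbols were.

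The non-normalized table holds 24526 lines with a probe ID, a bead address and a symbol that do not all belong together: probe ID and bead address named the same probe in 721 lines, and bead address and symbol in 24479. Signals of the 15 arrays of experiments 1 and 2 followed the probe ID and those of the 16 arrays of experiment 3 followed the bead address. With that key each array's signals had a Spearman correlation across probes of at least 0.9998 with its own column of the authors' normalized table, against at most 0.123 with the other key. The median correlation between arrays of experiments 1 and 2 and those of experiment 3 was 0.943 after matching and 0.116 as deposited. All values rest on the matched table, which holds 24518 probes. Of 18412 symbols, 15314 were current in the RefSeq gene table, 2488 were updated through a synonym and 610 were kept as given.

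Signals were background-corrected with the normexp model, with background parameters inferred from the detection p-values, an offset of 16, quantile normalization and log2 (limma neqc, limma 3.58.1, R 4.3.3; tables were read with version 1.17.8 of data.table). Probes with detection p under 0.01 on at least 2 arrays were kept (11843). For each of 9877 genes the probe with the highest mean was used; 1598 genes had more than 1 such probe, and where another probe of a named gene moved oppositely in Survivors this is stated. NFKBIA, IL6, ICAM1, TNFSF10 and TNFRSF11B had no passing probe. Between 36.8 and 45.9% of probes were detected per array, and the median raw signal ranged from 49.9 to 102.

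Differences were tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes within a comparison, threshold 0.05) in 1 fit of all arrays with 10 groups and experiment as a fixed term. The fit had 19 residual and 4.53 prior degrees of freedom. Differences of TRAIL effects are contrasts of 4 groups in that fit. Values are log2 differences with SE. A named gene undetected on every array of 1 group is given as a lower bound of the fold, and without a size where a difference of TRAIL effects includes such a group; list medians at bounds hold such genes at that bound and leave out genes undetected in both groups. Such medians were not computed for differences of TRAIL effects. A gene detected on only some arrays of a group keeps a size with SE, which the floor can limit. Lists of genes were tested with camera (preset correlation 0.01, and an estimated correlation beside it), with Benjamini-Hochberg over 435 tests of 29 lists and 15 comparisons. Of these 117 passed, and 7 passed with an estimated correlation: acute-phase genes in Survivors, in Reset versus Survivors and in the 3 differences of the TRAIL effect from parental cells, cholesterol biosynthesis in Repeat, and glycolysis and hypoxia genes in IKB_control. Similarity of effects was measured by Pearson's r across genes, set against 20 simulated data sets without effects and with the Control arrays split where they were shared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

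Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For survivor and recovery comparisons with control the rule names the 10 largest increases and the 10 largest decreases that passed with the same sign in every experiment, for the other comparisons the 5 largest of each, for each list up to 4 passing members, and 14 death-receptor and NF-kB genes in any case; genes named once could be followed elsewhere. Alternatives were the authors' normalized table, no background correction, no detection filter, no experiment term, a replicate block, group by experiment as a random block, arrays averaged per group and experiment, an intensity trend, only the compared arrays, only experiment 3 for differences, no Survivors arrays with conflicting texts, and each array left out in turn. Chosen after seeing the data were the table as deposited without matching, removal of experiment 1, experiment 3 alone, a crossed replicate block and a block for pairs by order within experiment. The pipeline was tested on simulated data with 200 of 9877 genes changed: log2 changes of 0.5, 1 and 2 were recovered for 81.5, 98.5 and 99.5% of genes in Survivors versus Control, 68.5, 94.0 and 99.5% in Reset versus Control, and 27.0, 89.0 and 99.0% in IETD_survivors versus IETD_control, with 2 to 11 false calls. Left out were the unmatched columns of the second normalized table and a block for the chip.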

Results

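Gene expression was measured in MCF10A cells, a nontransformed human breast epithelial line, after exposure to TRAIL, a cytokine that binds death receptors and activates caspase-8. Total RNA was hybridised to Illumina Ref8 BeadChips, with 1 array per sample and 31 arrays in all. Parental cells gave 7 Control and 6 Survivors arrays, the latter from the 10 to 20% of cells alive 1 day after 6 h with 50 ng/ml TRAIL. They also gave 3 Reset arrays (survivors 7 days after treatment) and 3 Repeat arrays (survivors treated again on days 1 and 2). Survivors replicates 5 and 6 were grouped by title, and for them no day or surviving percent was taken since their texts name Reset and Repeat treatment. Cells with a stable IKB super-repressor, which blocks NF-kB, and cells given the caspase inhibitors IETD or zVAD each gave 2 control arrays and 2 survivor arrays. The arrays came from 3 experiments on different days, and all IKB and inhibitor arrays belonged to experiment 3. The percent of probes detected per array ranged from 36.8 to 45.9. The p-values measure the spread between these samples, for which the labels do not say whether replicates within an experiment were separate cultures. For the IKB and inhibitor groups, all of experiment 3, they do not measure how an effect varies between experiments. Their tests rest on a spread pooled over all groups. Counts with arrays averaged per group and experiment are given in the closing part on processing. Control arrays of experiment 1 varied most, with an SD of the log2 difference between replicates of 0.42 to 0.49, against 0.14 to 0.21 for replicate pairs of experiments 2 and 3.

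Which transcripts distinguish cells that lived through TRAIL from untreated cells was addressed by Survivors (n = 6) versus Control (n = 7). CFB, a complement protease, rose by 4.46 ± 0.35 on the log2 scale (SE; 22-fold, adjusted p = 3.06e-09), and S100A8, a subunit of calprotectin, by 3.25 ± 0.24 (adjusted p = 1.11e-09). LCN2, an iron-sequestering antimicrobial protein, was at least 5.23-fold higher (adjusted p = 1.03e-13) and SAA2 at least 5.44-fold (adjusted p = 4.18e-11). IL32 was at least 5.12-fold higher (adjusted p = 4.18e-11) and PDZK1IP1 at least 3.75-fold (adjusted p = 1.97e-11). These 4 genes were detected on no Control array. Each such fold sets the mean of the group with signal against the other group, with its signals raised to the lowest detected signal of their array where they lay below it. TGM2, a transglutaminase, rose by 3.26 ± 0.25 (adjusted p = 1.32e-09, and 0.78 for its other probe) and SPRR2A of the cornified envelope by 3.20 ± 0.23 (adjusted p = 6.97e-10). The elastase inhibitor PI3 (3.06 ± 0.22, adjusted p = 9.64e-10) and the gelatinase MMP9 (2.87 ± 0.28, adjusted p = 7.85e-08) completed the 10 largest increases. MMP9 was detected on 1 and SPRR2A on 2 of 7 Control arrays, so the floor limits both sizes.

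The decreases in Survivors were smaller. PHGDH, which starts serine synthesis, fell by 1.39 ± 0.08 on the log2 scale (adjusted p = 4.18e-11). The imprinted noncoding RNA H19 fell by 1.54 ± 0.14 (adjusted p = 3.16e-08), and CAMK2B fell by 1.71 ± 0.38 (adjusted p = 0.00147). NUDT1 (-1.31), ACOX2 (-1.27), PEG10 (-1.08), ETV4 (-1.05), GLS2 (-1.01), the receptor tyrosine kinase AXL (-1.0) and TNNI2 (-0.98) were the other large decreases. Their adjusted p ranged from 1.19e-09 (NUDT1) to 6.7e-05 (GLS2). Each of these 20 genes moved in its fitted direction on all 6 Survivors arrays against Control arrays of the same experiment. The rule that named them required the same sign in every experiment, so this was largely fixed in advance. In total 3247 of 9877 genes passed an adjusted p of 0.05 in limma, 1435 higher and 1812 lower. Changes of at least 2-fold were 153 increases and 9 decreases. Within experiments 1, 2 and 3 alone, 959, 2503 and 754 genes passed, and 96.0, 99.5 and 99.1% of the pooled calls had the same sign there. The same arrays had made the pooled calls, so agreement in sign was partly built in. The size of the response differed between experiments for 312 genes (test of interaction; 1578 at an unadjusted p under 0.05).

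**Figure D1:**
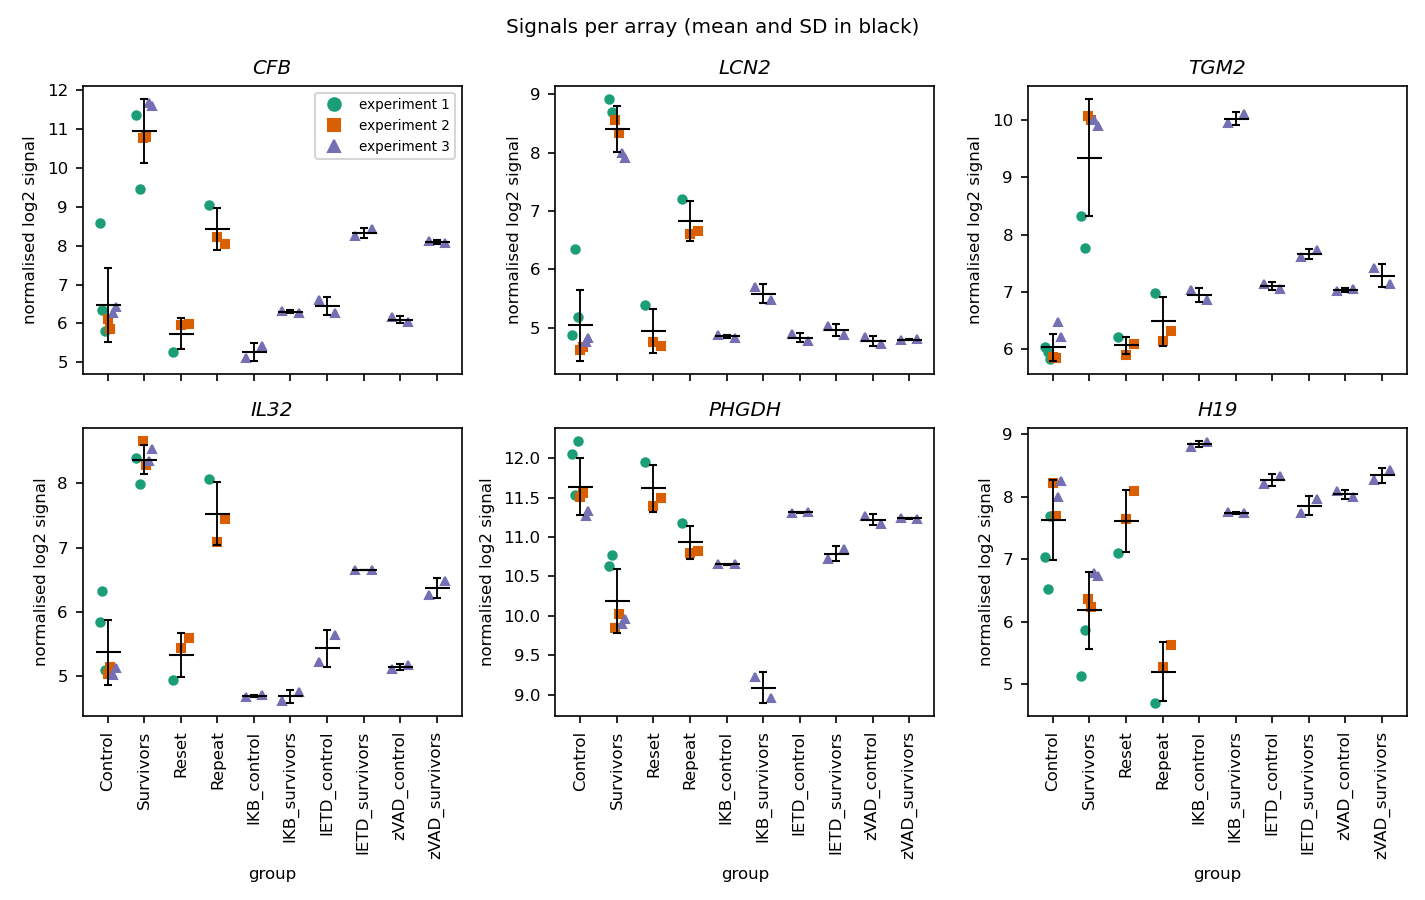
Normalised log2 signals of CFB, LCN2, TGM2, IL32, PHGDH and H19 on every array, marked by experiment, with group mean and SD. CFB averaged 6.48 in Control, 10.94 in Survivors, 5.74 in Reset and 8.43 in Repeat.

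All 17 measured genes of the acute-phase and antimicrobial defence list rose in Survivors (17 when adjusted over the list alone), with a median log2 difference of 2.37 (2.07 with genes undetected in 1 group at their bound). The list moved relative to all other genes (camera adjusted p = 9.31e-25, and adjusted p = 0.0193 with an estimated correlation). Cytokines and chemokines had 15 of 16 genes higher (15 adjusted over the list alone, median 1.3, at bounds 0.99; adjusted p = 2.28e-10), such as CSF3 (1.42 ± 0.26) and IL1B (1.45 ± 0.34). The list had adjusted p = 0.244 with an estimated correlation. NF-kB target genes had 17 of 28 higher and 11 not passed (18 adjusted over the list alone, median 0.79, at bounds 0.70; adjusted p = 7.98e-09), such as SOD2 (2.80 ± 0.24, adjusted p = 9.52e-09) and CXCL1 (2.23 ± 0.45). It had adjusted p = 0.39 with an estimated correlation. Interferon-stimulated genes had 17 of 23 higher and 6 not passed (20 adjusted over the list alone, median 0.79, at bounds 0.51; adjusted p = 1.28e-11), such as IFI27 (2.36 ± 0.26). This list had adjusted p = 0.22 with an estimated correlation. Within experiments 1, 2 and 3 the medians were 1.80, 2.78 and 2.30 for acute-phase genes, 0.44, 1.06 and 0.89 for NF-kB targets, and 0.39, 1.35 and 0.43 for interferon-stimulated genes.

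All 29 genes of the G2/M list fell in Survivors (29 adjusted over the list alone, median log2 difference -0.61; adjusted p = 1.25e-14, and adjusted p = 0.39 with an estimated correlation), such as CENPF (-0.93 ± 0.12, adjusted p = 5.11e-06), CDC25C (-0.83 ± 0.13) and DLGAP5 (-0.83). The medians within experiments 1, 2 and 3 were -0.20, -1.15 and -0.55. Of 26 genes of the G1/S and DNA replication list 14 fell and 12 did not pass (16 lower and 1 higher adjusted over the list alone, median -0.34; adjusted p = 0.00145), such as MCM2 (-0.50 ± 0.12) and TYMS (-0.50 ± 0.10). The list had adjusted p = 0.758 with an estimated correlation.

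Epidermal differentiation genes had 14 of 17 higher and 3 not passed (14 adjusted over the list alone, median 1.14, at bounds 1.11; adjusted p = 6.66e-09), such as SPRR2D (2.47 ± 0.42). It had adjusted p = 0.304 with an estimated correlation. Basal epithelial markers had 16 of 22 higher and 6 not passed (16 adjusted over the list alone, median 0.41; adjusted p = 2.71e-06), such as the keratins KRT6B (2.64 ± 0.47) and KRT16 (1.40 ± 0.26). This list had adjusted p = 0.304 with an estimated correlation. Extracellular proteases and inhibitors had 10 of 22 higher, 1 lower and 11 not passed (11 and 1 adjusted over the list alone, median 0.38, at bounds 0.31; adjusted p = 4.57e-05), such as MMP7 (1.89 ± 0.23) and SERPINB2 (2.32 ± 0.43). The list had adjusted p = 0.304 with an estimated correlation.

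Genes that set the response to death receptors were also followed in Survivors. CFLAR, which encodes the caspase-8 inhibitor FLIP, rose by 0.86 ± 0.15 (adjusted p = 0.000148), the ubiquitin ligase BIRC3 by 0.80 ± 0.23 (adjusted p = 0.0105, in its direction on 5 of 6 arrays) and BID by 0.26 ± 0.07. The decoy receptor TNFRSF10D fell by 0.29 ± 0.11 (adjusted p = 0.0473, in its direction on 4 of 6 arrays), a call that ended in 6 of the alternatives, the deposited normalized table among them. CASP8 differed by -0.25 (adjusted p = 0.064), TNFRSF10A, TNFRSF10B (0.03, and -0.13 and -0.21 for its other probes) and TNFAIP3 (0.60 ± 0.40, adjusted p = 0.268) did not pass, although TNFAIP3 passed in experiment 3 alone (1.52, adjusted p = 0.000266), and TNFRSF10C was undetected in both groups. The list of TRAIL receptors and death-receptor signalling had 3 higher, 1 lower and 12 not passed of 16 (3 and 0 adjusted over the list alone, median 0.04; adjusted p = 0.513). The BCL2 family list had 5 higher, 2 lower and 13 not passed of 20 (5 and 2 adjusted over the list alone, median 0.04; adjusted p = 0.503), MCL1 among the lower (-0.43 ± 0.12). Without Survivors replicates 5 and 6, whose texts conflict, BIRC3 lost its call.

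Whether the survivor profile persisted after a week was addressed by Reset (n = 3) versus Control (n = 7). No gene passed in limma (0 of 9877; 257 at an unadjusted p under 0.05), and the smallest adjusted p was 0.999. On the log2 scale the 95% interval was -1.50 to 0.38 for CFB, -0.87 to 0.42 for S100A8 and -0.24 to 0.21 for PHGDH, and H19 differed by 0.00 ± 0.18. LCN2 and IL32 were detected on no Reset or Control array. In simulated data of this design a log2 change of 1 was recovered for 94.0% of genes and one of 0.5 for 68.5%, and smaller changes were not simulated. The changed genes were drawn at random, so these shares do not apply to genes with larger spread, such as CFB. NF-kB target genes had a median of -0.36 (at bounds -0.43, adjusted p = 4.33e-10, and adjusted p = 0.381 with an estimated correlation), but 0 of 28 passed in limma (0 adjusted over the list alone). The median was -0.65 within experiment 1 (1 Reset array) and -0.09 within experiment 2 (2 Reset arrays).

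Against Survivors (n = 6), Reset cells (n = 3) had 2763 genes that passed in limma, 1524 higher and 1239 lower, of which 14 were higher and 237 lower by at least 2-fold. CFB fell by 5.02 ± 0.47 on the log2 scale (adjusted p = 9.99e-08), LCN2 was at least 4.90-fold lower (adjusted p = 3.3e-11) and S100A8 fell by 3.47 ± 0.32. H19 rose by 1.54 ± 0.19 (adjusted p = 4.34e-06), PHGDH by 1.38 ± 0.11 (adjusted p = 1.25e-08) and the calcium-dependent kinase subunit CAMK2B by 2.08 ± 0.50 (adjusted p = 0.00387). All 17 acute-phase genes were lower (17 adjusted over the list alone, median -2.51, at bounds -2.0; adjusted p = 6.18e-24, and adjusted p = 0.0193 with an estimated correlation). Of the G2/M genes 27 of 29 were higher and 2 did not pass (28 adjusted over the list alone, median 0.76; adjusted p = 1.81e-13, and adjusted p = 0.39 with an estimated correlation). CFLAR fell by 1.33 ± 0.20 (adjusted p = 5.09e-05). Within experiment 2 alone (2 Reset arrays) 2397 genes passed. Within experiments 1 (1 Reset array) and 2, 98.5 and 100% of pooled calls had the same sign, though the same arrays had made those calls. Without Reset replicate 1 the count was 1549.

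Whether further TRAIL deepened or altered the survivor profile was addressed by Repeat (n = 3) versus Control (n = 7). The labels give no harvest day or surviving percent for Repeat. Further TRAIL therefore cannot be told apart from a longer time since the first TRAIL, here or in the comparison of Repeat with Survivors. HSD17B2, which inactivates sex steroids, rose by 3.33 ± 0.46 on the log2 scale (10.1-fold, adjusted p = 5.92e-05). The neutrophil chemokines CXCL1 (2.52 ± 0.58, adjusted p = 0.0081) and CXCL2 (2.37 ± 0.51, adjusted p = 0.00465) and the growth factor CSF3 (2.29 ± 0.34, adjusted p = 0.00014) were among the largest increases. IL32 was at least 2.86-fold higher (adjusted p = 3.25e-06), LCN2 at least 1.75-fold (adjusted p = 2.36e-06), and CFB rose by 2.14 ± 0.45 (adjusted p = 0.0044). H19 was at least 3.10-fold lower (adjusted p = 1.04e-08), and DMBT1 (-1.58 ± 0.12, adjusted p = 1.04e-08), the transcription factor SOX9 (-1.51 ± 0.25) and HMGCS1 of the mevalonate pathway (-1.50 ± 0.19, adjusted p = 2.02e-05) fell. In total 802 genes passed, 357 higher and 445 lower, of which 54 were higher and 33 lower by at least 2-fold. The 20 genes of largest change moved in their direction on all 3 Repeat arrays, which the rule that named them largely fixed in advance. Within experiment 2 alone (2 Repeat arrays) 256 genes passed. Within experiments 1 and 2 the sign matched 99.5 and 99.8% of the pooled calls, which the same arrays had made. Between the experiments 68 genes differed in response, with 1 Repeat array in experiment 1. Without Repeat replicate 1 the count was 282.

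Cholesterol biosynthesis genes were lower in Repeat cells. Of 21 genes 15 fell and 6 did not pass (19 adjusted over the list alone, median -0.55; adjusted p = 4.31e-18, and adjusted p = 0.0372 with an estimated correlation), such as DHCR7 (-0.98 ± 0.12), IDI1 (-0.96 ± 0.14) and INSIG1 (-1.10 ± 0.15). INSIG1 was detected on 1 of 3 Repeat arrays, so the floor limits its size. Medians of the list were -0.82 and -0.49 within experiments 1 and 2. In Survivors the list had 2 higher, 4 lower and 15 not passed (2 and 4 adjusted over the list alone, median -0.07, at bounds 0.00, test direction higher; adjusted p = 0.963). NF-kB target genes had 13 of 28 higher and 15 not passed in Repeat (15 higher and 1 lower adjusted over the list alone, median 0.84; adjusted p = 5.25e-09, and adjusted p = 0.39 with an estimated correlation). Acute-phase genes had 11 of 17 higher and 6 not passed (12 adjusted over the list alone, median 0.82; adjusted p = 7.02e-10, and adjusted p = 0.22 with an estimated correlation). Cytokines had 8 of 16 higher and 8 not passed (10 adjusted over the list alone, median 1.20, at bounds 1.21; adjusted p = 8.17e-07, and adjusted p = 0.335 with an estimated correlation). Of the 29 G2/M genes 0 passed in limma against Control (0 adjusted over the list alone, median 0.17; adjusted p = 0.0064, and adjusted p = 0.79 with an estimated correlation).

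Compared directly with Survivors (n = 6), Repeat cells (n = 3) had 2144 genes that passed, 1089 higher and 1055 lower, of which 14 were higher and 149 lower by at least 2-fold. SPRR2A fell by 2.90 ± 0.30 on the log2 scale (adjusted p = 1.96e-06), MMP9 fell by 2.77 ± 0.37 (adjusted p = 2.4e-05) and TGM2 fell by 2.71 ± 0.33 (adjusted p = 8.65e-06). The cystine transporter SLC7A11 rose by 1.35 ± 0.25 (adjusted p = 0.000559) and HSD17B2 by 1.52 ± 0.48 (adjusted p = 0.0251). The floor limits the sizes of SLC7A11, detected on 1 of 6 Survivors arrays, and of SPRR2A and MMP9, each detected on 1 of 3 Repeat arrays. All 29 G2/M genes were higher (29 adjusted over the list alone, median 0.81; adjusted p = 1.49e-19, and adjusted p = 0.322 with an estimated correlation). Acute-phase genes had 14 of 17 lower and 3 not passed (14 adjusted over the list alone, median -1.44, at bounds -1.30; adjusted p = 1.81e-13, and adjusted p = 0.0965 with an estimated correlation). Cholesterol genes had 15 of 21 lower and 6 not passed (15 lower and 1 higher adjusted over the list alone, median -0.60; adjusted p = 2.78e-11, and adjusted p = 0.187 with an estimated correlation). For NF-kB target genes 2 were higher, 8 lower and 18 not passed (2 and 8 adjusted over the list alone), with a median of 0.14 but a test direction of lower (adjusted p = 0.498). Within experiment 2 alone (2 Repeat arrays) 2496 genes passed. Within experiments 1 (1 Repeat array) and 2, 96.0 and 100% of pooled calls had the same sign, though the same arrays had made those calls. The count was 1409 without Survivors replicate 4, 1280 without Repeat replicate 3 and 3485 without experiment 1.

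**Figure D2:**
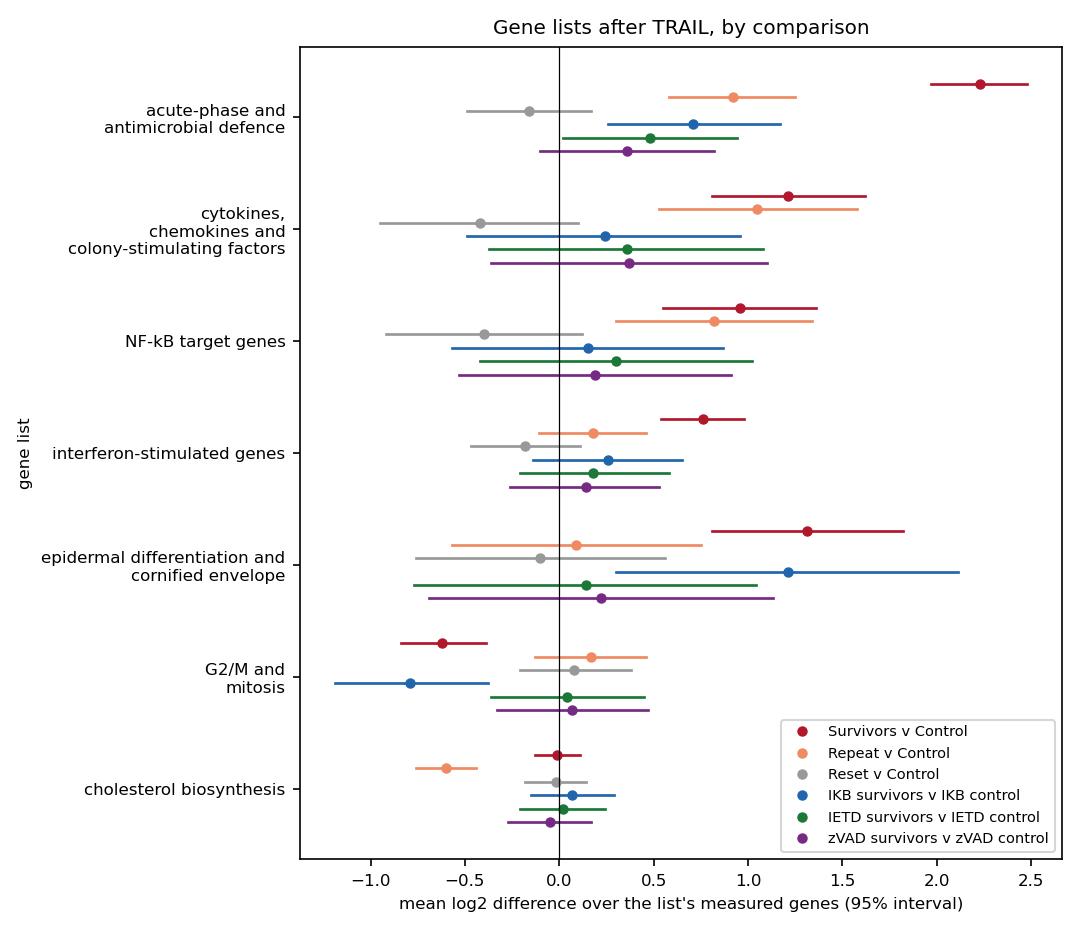
Mean log2 difference with 95% interval of 7 gene lists in 6 comparisons. Acute-phase genes averaged 2.23 (1.97 to 2.48) in Survivors, 0.92 (0.58 to 1.25) in Repeat, 0.71 (0.26 to 1.17) in IKB survivors and 0.36 (-0.10 to 0.82) in zVAD survivors.

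The part of the survivor profile that needs NF-kB was addressed with IKB super-repressor cells (n = 2 arrays per group, experiment 3). For IKB survivors the labels give a day but no TRAIL dose, hours of treatment or surviving percent. A difference from parental cells in these or in the cell line is therefore not separated from the block of NF-kB. IKB survivors versus IKB control cells again had higher TGM2 (3.08 ± 0.44 on the log2 scale, adjusted p = 0.000364, and 0.26 for its other probe) and lower PHGDH (-1.57 ± 0.15, adjusted p = 1.4e-06) and H19 (-1.10 ± 0.25, adjusted p = 0.0164). The small heat-shock protein CRYAB was at least 7.19-fold higher (adjusted p = 2.83e-05), the protease MMP7 at least 5.54-fold (adjusted p = 0.000364), and the linker histone gene H1-2 rose by 2.15 ± 0.29 (adjusted p = 0.000244). CFB, detected on both IKB survivor arrays and no IKB control array, did not pass (at least 1.47-fold, adjusted p = 0.412), and LCN2, IL32 and MMP9 were detected on no array of either IKB group. In total 374 genes passed in limma, 153 higher and 221 lower, of which 48 were higher and 13 lower by at least 2-fold. The count was 79 without IKB_control replicate 1, 17 without IKB_control replicate 2, 72 without IKB_survivors replicate 1 and 28 without IKB_survivors replicate 2, where a lone array is assumed to vary like the other groups. The 20 genes of largest change moved in their direction on both IKB survivor arrays. Those arrays had also selected the genes, so this is no separate evidence. When the arrays of experiment 3 were fitted alone, without the more variable arrays of experiment 1, 1734 genes passed.

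By list, NF-kB target genes of IKB survivors had 0 higher, 1 lower and 27 not passed of 28 (0 and 1 adjusted over the list alone, median 0.04, at bounds 0.07; adjusted p = 0.541). Acute-phase genes had 3 of 17 higher and 14 not passed (8 adjusted over the list alone, median 0.59, at bounds 0.48; adjusted p = 1.96e-06, and adjusted p = 0.309 with an estimated correlation), SAA1 (1.56 ± 0.36) and SERPINA3 (1.16 ± 0.26) among them. G2/M genes had 21 of 29 lower and 8 not passed (29 adjusted over the list alone, median -0.79; adjusted p = 6.18e-24, and adjusted p = 0.304 with an estimated correlation), such as PLK1 (-0.96 ± 0.20). Epidermal differentiation genes had 1 of 17 higher and 16 not passed (11 adjusted over the list alone, median 1.12, at bounds 1.38; adjusted p = 2.8e-07, and adjusted p = 0.363 with an estimated correlation). In experiment 3 alone 14 of these 17 epidermal genes, 12 of 17 acute-phase genes and 5 of 28 NF-kB target genes (2 lower) were higher, and all 29 G2/M genes were lower.

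The direct test of the TRAIL effect in IKB cells minus that in parental cells called 27 genes, 3 higher and 24 lower (7 higher and 18 lower in the deposited normalized table). SOD2, a mitochondrial superoxide dismutase, had a log2 difference of -2.75 ± 0.48 (adjusted p = 0.00891). LCN2 (adjusted p = 2.79e-05), IL32 (adjusted p = 0.000111), MMP9 (adjusted p = 0.0251) and CFB (adjusted p = 0.033) also had a smaller effect in IKB cells, and no size is given since they were undetected in IKB control cells. TGM2 (-0.18 ± 0.50), PHGDH (-0.17 ± 0.17) and CENPF (-0.07 ± 0.25) did not pass, and the mean of the G2/M list differed by -0.17 (95% interval -0.63 to 0.29). Acute-phase genes had 6 of 17 lower and 11 not passed (13 adjusted over the list alone, median -1.45; adjusted p = 1.95e-29, and adjusted p = 0.0168 with an estimated correlation). NF-kB target genes had 4 of 28 lower and 24 not passed (7 adjusted over the list alone, median -0.74; adjusted p = 1.97e-11, and adjusted p = 0.361 with an estimated correlation). Interferon-stimulated genes had 1 of 23 lower and 22 not passed (5 adjusted over the list alone, median -0.40; adjusted p = 1.25e-10, and adjusted p = 0.255 with an estimated correlation). The parental effect pools 3 experiments, while IKB arrays came from experiment 3 only. The interferon list had a median of 0.41 and 0.52 on Survivors replicates 5 and 6 of experiment 3, against 0.85 over experiments 1 and 2. Part of the -0.40 can therefore stem from experiments without IKB arrays. The count was 196 in experiment 3 alone, with 13 of 17 acute-phase and 11 of 28 NF-kB target genes lower, and 250 without experiment 1. Without Survivors replicates 5 and 6 the count was 8 and CFB, MMP9 and SOD2 lost their calls. The count was 43 without Control replicate 1, 74 without Survivors replicate 2 and 16 without Survivors replicate 5, and with 1 array left out from the IKB groups it was 6, 6, 5 and 6 (IKB_control replicates 1 and 2, IKB_survivors replicates 1 and 2).

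Before TRAIL, IKB control cells (n = 2) differed from Control (n = 7) in 69 genes, 30 higher and 39 lower (31 higher and 18 lower in the deposited normalized table). The keratin gene KRT13 rose by 3.88 ± 0.54 (adjusted p = 0.000164) and CDA, a cytidine deaminase, by 2.40 ± 0.26 (adjusted p = 5.35e-06). S100A8 fell by 2.06 ± 0.39 (adjusted p = 0.00745) and NFKB1 fell by 0.37 ± 0.09 (adjusted p = 0.0438). RAB31 was at least 3.25-fold lower (adjusted p = 5.23e-08). NF-kB target genes had 2 of 28 lower and 26 not passed (4 adjusted over the list alone, median -0.41, at bounds -0.60; adjusted p = 9.53e-06, and adjusted p = 0.582 with an estimated correlation). The glycolysis and hypoxia list was higher with 0 of 24 genes passing in limma (3 adjusted over the list alone, median 0.20; adjusted p = 4.88e-05, and adjusted p = 0.0214 with an estimated correlation). The count was 40 without Control replicate 7, 29 without IKB_control replicate 1, 23 without IKB_control replicate 2, 34 without Survivors replicates 5 and 6, 377 in experiment 3 alone and 445 without experiment 1.

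Whether the profile needs caspase activity was addressed with IETD, which targets caspase-8, and zVAD, which targets caspases broadly; doses were not given, and all cells survived per the labels. With IETD, 0 genes passed between IETD survivors and IETD control cells (n = 2 each; limma; 550 at an unadjusted p under 0.05), and with zVAD 0 genes passed (n = 2 each; limma; 1166 at an unadjusted p under 0.05). Differences on the log2 scale with IETD were 1.89 ± 0.63 for CFB (adjusted p = 0.819; 95% interval 0.59 to 3.19), 0.57 for TGM2 (-0.34 to 1.48) and -0.53 for PHGDH (-0.84 to -0.22). With zVAD they were 2.00 ± 0.63 for CFB (adjusted p = 0.22; 0.70 to 3.30), 0.25 for TGM2 (-0.66 to 1.15) and 0.02 for PHGDH (-0.29 to 0.33). IL32, undetected in both inhibitor control groups and detected on all 4 survivor arrays, was at least 1.99-fold higher with IETD (adjusted p = 0.787) and 1.61-fold with zVAD (adjusted p = 0.194), and LCN2 was detected on none of the 8 inhibitor arrays. When the arrays of experiment 3 were fitted alone, 30 genes passed with IETD and 103 with zVAD, with CFB (adjusted p = 4.2e-06 and 2.04e-06) and IL32 (0.000362 and 0.000308) higher in both. In simulated data of the IETD design a log2 change of 1 was recovered for 89.0% of genes. The changed genes were drawn at random from all genes, whose median SE in this comparison was 0.155. The share does not apply to genes with larger spread, such as CFB. Acute-phase genes had 0 of 17 passing in limma with IETD (1 adjusted over the list alone, median 0.32, at bounds 0.40; adjusted p = 5.41e-05, and adjusted p = 0.385 with an estimated correlation) and 0 of 17 with zVAD (median 0.21, at bounds 0.25; adjusted p = 0.0355, and adjusted p = 0.681 with an estimated correlation). In experiment 3 alone 5 of the 17 acute-phase genes were higher with IETD, such as SAA1 (1.22, adjusted p = 0.000621) and S100A8 (1.05, adjusted p = 0.000362), and 2 of 17 with zVAD.

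The TRAIL effect with an inhibitor was tested directly against that in cells without inhibitor. With IETD 150 genes differed, 55 higher and 95 lower, of which 6 were higher and 44 lower by at least 2-fold. LCN2 (adjusted p = 1.16e-06) and IL32 (adjusted p = 0.0212), both undetected in Control and IETD control cells and so given without a size, had a smaller effect. TGM2 (-2.69 ± 0.50, adjusted p = 0.0118) was lower and PHGDH (0.87 ± 0.17, adjusted p = 0.0151) higher, while CFB did not pass (-2.57 ± 0.72, adjusted p = 0.066) except in experiment 3 alone (-3.40, adjusted p = 5.84e-08). Acute-phase genes had 9 of 17 lower and 8 not passed (16 adjusted over the list alone, median -1.77; adjusted p = 1.88e-21, and adjusted p = 0.0214 with an estimated correlation). G2/M genes had 2 of 29 higher and 27 not passed (26 adjusted over the list alone, median 0.65; adjusted p = 2.22e-14, and adjusted p = 0.39 with an estimated correlation), such as TOP2A (0.90 ± 0.23). The count rested on single arrays. It was 8 without either IETD_control replicate, 9 and 36 without IETD_survivors replicates 1 and 2, and 445, 300, 79, 61, 68 and 93 without Control replicates 1, 2, 4, 5, 6 and 7. For Survivors replicates 1 to 6 it was 285, 384, 58, 55, 66 and 67 without each in turn, and it was 48 without replicates 5 and 6 together. It was 998 in experiment 3 alone, with 16 of 17 acute-phase genes lower and 25 of 29 G2/M genes higher, and 2053 without experiment 1.

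With zVAD the effect differed for 708 genes, 387 higher and 321 lower, of which 15 were higher and 92 lower by at least 2-fold. LCN2, undetected in Control and both zVAD groups, had a smaller effect (adjusted p = 6.14e-07). TGM2 (-3.01 ± 0.50, adjusted p = 0.00213), S100A8 (-3.00 ± 0.49, adjusted p = 0.00185) and CFB (-2.46 ± 0.72, adjusted p = 0.0404) were lower, and PHGDH (1.41 ± 0.17, adjusted p = 9.62e-05) and H19 (1.85 ± 0.29, adjusted p = 0.00107) higher. CFLAR was lower as well (-1.08 ± 0.31, adjusted p = 0.0365). Acute-phase genes had 13 of 17 lower and 4 not passed (15 adjusted over the list alone, median -2.01; adjusted p = 3.31e-18, and adjusted p = 0.0372 with an estimated correlation). G2/M genes had 11 of 29 higher and 18 not passed (23 adjusted over the list alone, median 0.69; adjusted p = 4.84e-12, and adjusted p = 0.435 with an estimated correlation), such as PLK1 (1.11 ± 0.23). The count was 1209 without Control replicate 1, 465 without Control replicate 4, 441 without Survivors replicate 4, 299 and 34 without zVAD_control replicates 1 and 2, and 61 and 84 without zVAD_survivors replicates 1 and 2. It was 1010 in experiment 3 alone and 2459 without experiment 1.

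The IETD and zVAD effects differed from each other for 3 genes, among them ARPP19 (1.25 ± 0.22) and ADAR (0.72 ± 0.13, whose other probe moved oppositely in Survivors), both higher with IETD (adjusted p = 0.0351 for each). In experiment 3 alone, which holds all arrays of this contrast, 349 genes differed, 213 higher and 136 lower, KRT16 among them (1.24, adjusted p = 0.0381). Mean log2 levels of ADAR were 10.96 in IETD control and 11.29 in zVAD control cells, and 11.31 and 10.92 in the survivors. For ARPP19 they were 10.14 and 10.63 in the controls, and 10.58 and 9.82 in the survivors. For KRT16 they were 8.57 and 9.45, and 9.45 and 9.09. The inhibitor control groups thus differed for these genes without TRAIL, and that offset is part of each contrast. The count was 0 without IETD_survivors replicate 1, either IETD_control replicate, zVAD_survivors replicate 1 or either zVAD_control replicate, 49 without IETD_survivors replicate 2, 7 without zVAD_survivors replicate 2 and 0 without Survivors replicates 5 and 6. The 95% interval of the difference was -1.94 to 1.73 for CFB, -0.96 to 1.61 for TGM2 and -0.98 to -0.10 for PHGDH (adjusted p = 0.222), so sizeable differences between the inhibitors were not excluded for CFB and TGM2. The mean of the acute-phase list differed by 0.12 (-0.53 to 0.77).

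Given alone, IETD (n = 2) differed from Control (n = 7) in 825 genes, 355 higher and 470 lower, of which 3 were higher and 10 lower by at least 2-fold. OLR1, a lectin-like receptor, rose by 2.20 ± 0.39 (adjusted p = 0.00184), RELB by 1.10 ± 0.32 (adjusted p = 0.0358) and NFKB1 by 0.65 ± 0.09 (adjusted p = 0.000179), and TSC22D3 fell by 1.65 ± 0.37 (adjusted p = 0.00894). NF-kB target genes had 3 of 28 higher and 25 not passed (3 adjusted over the list alone, median 0.48, at bounds 0.54; adjusted p = 0.00419, and adjusted p = 0.727 with an estimated correlation). The count was 367 without Control replicate 6, 334 without Control replicate 7, 133 without IETD_control replicate 1, 212 without IETD_control replicate 2, 497 without Survivors replicates 5 and 6, 2309 in experiment 3 alone and 2241 without experiment 1. For zVAD alone (n = 2) 37 genes passed, 24 higher and 13 lower, PRR15L (-1.42 ± 0.30, adjusted p = 0.03) and AHNAK (0.95 ± 0.17, adjusted p = 0.0299; its other probes moved oppositely in Survivors) among them. That count was 151 without Control replicate 1, 95 without Control replicate 2, and 0 without Control replicate 6 or 7, either zVAD_control replicate, or Survivors replicates 5 and 6. It was 636 in experiment 3 alone and 676 without experiment 1. Mean log2 levels in IETD control and zVAD control cells were 7.53 and 6.67 for OLR1, 7.77 and 7.33 for RELB, and 12.37 and 12.05 for NFKB1. For TSC22D3 they were 7.19 and 7.42. Control averaged 5.88, 6.89, 11.89 and 8.73 over its 3 experiments. The shifts named for IETD alone are thus not shown to be particular to IETD.

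**Figure D3:**
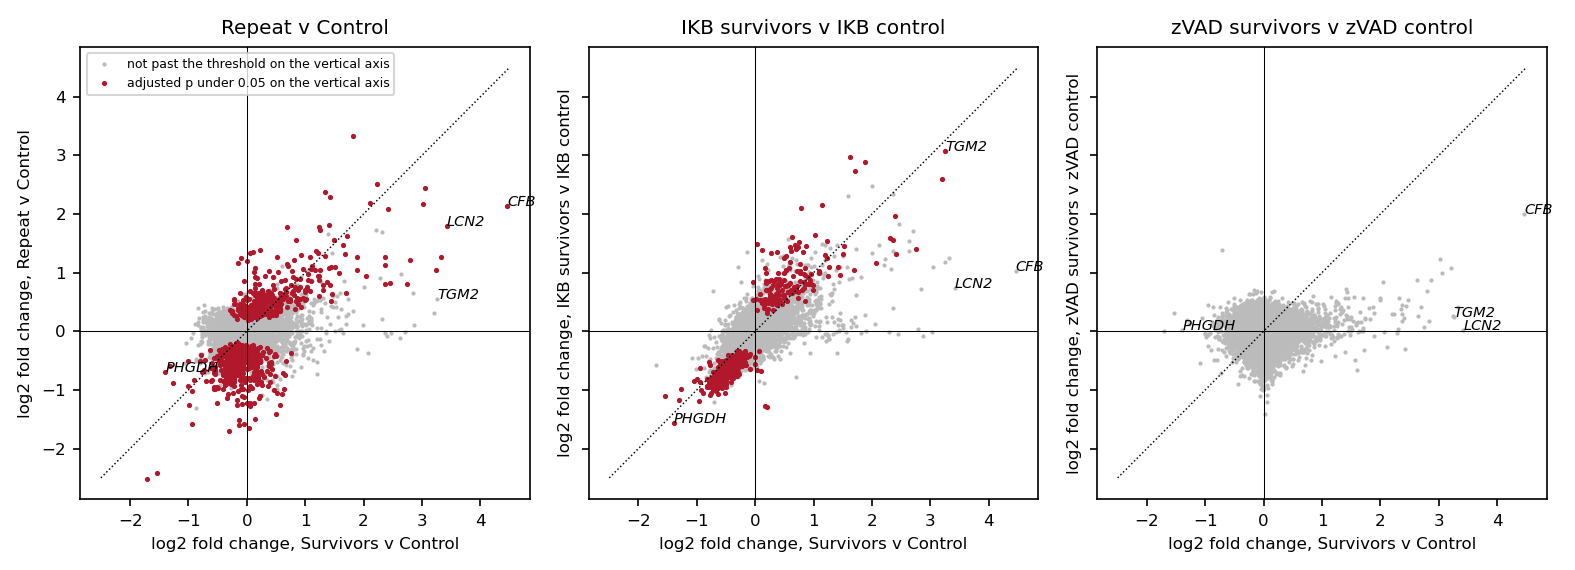
Log2 fold change of each gene in Survivors against that in Repeat, IKB survivors and zVAD survivors, with genes that passed on the vertical axis in red and a dotted line of equality. Pearson's r across genes was 0.40, 0.68 and 0.09.

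Across genes, which are not independent replicates, the Survivors and IKB survivors changes had a Pearson's r of 0.68 (jackknife SE 0.082), where simulated data without effects gave 0.00. In these comparisons 130 genes were higher in both (22.2 if independent), 202 lower in both (40.5) and 0 opposite. Survivors and Repeat shared Control arrays and had an r of 0.40 (jackknife SE 0.236) with a simulated value of 0.35, and a covariance of 0.0357 against a simulated 0.0053. With the Control arrays split between the comparisons r was 0.29 and the covariance 0.0281. In the fit with shared Control arrays, which raises overlap, 208 genes were higher in both (51.9 if independent), 138 lower in both (81.6) and 40 opposite. Survivors and IETD survivors had an r of 0.24 (jackknife SE 0.083, simulated 0.01), and Survivors and zVAD survivors an r of 0.09 (jackknife SE 0.059, simulated 0.00), which was 0.18 in experiment 3 alone.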

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

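Tests chosen after their result was seen were those of the inhibitors given alone, of Survivors replicates 5 and 6, of a compressed signal scale, and the splits for Reset versus Control.

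In 90 tests of a named gene in a group (Control or Survivors), 1 array lay far from the others in 9, and chance gives about 1 in 20. All 9 values came from arrays of experiment 1. On the log2 scale they were Control replicate 1 for CFB (8.58, others 5.80 to 6.42) and BIRC3 (11.17, others 9.47 to 9.97), Control replicate 2 for LCN2 (6.35, others 4.63 to 5.19), PI3 (11.26, others 8.92 to 9.79) and ACOX2 (9.65, others 10.32 to 10.69), Control replicate 3 for HSD17B2 (4.84, others 5.92 to 6.70) and SOX9 (6.25, others 7.40 to 8.21), and Survivors replicate 1 for GLS2 (5.09, others 5.68 to 5.97) and PHACTR3 (6.52, others 7.91 to 8.55).

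Effects differed between groups by direct tests in limma: the TRAIL effect in IKB cells minus that in parental cells for 27 genes, with IETD minus without inhibitor for 150, with zVAD minus without inhibitor for 708, and with IETD minus with zVAD for 3. The Survivors effect differed between experiments for 312 genes and the Repeat effect for 68.

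Acute-phase genes rose less after TRAIL with a caspase inhibitor, by a median of -1.77 with IETD and -2.01 with zVAD. A compressed signal scale on the inhibitor arrays was argued against by the slope of non-normalized log2 signals on Control, which was 1.003 with IETD and 0.952 with zVAD, beside 0.977 without inhibitor. A prior rise from the inhibitors alone was argued against by the list's medians with inhibitor alone, of which the higher was -0.17. Inhibited caspases, which the design names, stay open as a biological explanation, as does the difference that all inhibitor-treated cells survived, so that the arrays were not enriched for a surviving fraction. The design does not separate these explanations.

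No gene differed between Reset and Control in limma (0 of 9877; 257 at an unadjusted p under 0.05). Too few arrays to see changes of the size in Survivors was argued against, since 3 Survivors arrays of the same experiments gave 2264 genes (2522 with the other choice of array). In Reset the NF-kB target genes had a median of -0.36, with 0 of 28 passing in limma and adjusted p = 0.381 with an estimated correlation, and of -0.09 within experiment 2, a value that a contribution from the variable Control arrays of experiment 1 could give. Across genes the Survivors and Reset changes had an r of -0.35 (jackknife SE 0.314, simulated 0.36), and of -0.40 with the Control arrays split. The Reset changes of experiments 1 and 2 had an r of -0.192 with each other. A return of the cells to the Control state by day 7 stays open as a biological explanation and was not tested beyond these comparisons. Nor was a shift opposite to that of Survivors.

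The texts of Survivors replicates 5 and 6 name Reset and Repeat treatment. Replicate 5 had a median acute-phase difference of 2.25 against Control of experiment 3, where Survivors of experiments 1 and 2 had 2.28 and Reset -0.15, which argues against cells 7 days after TRAIL. Replicate 6 had a median G2/M difference of -0.54, where Survivors had -0.64 and Repeat 0.17, which argues against re-treated cells. Both changes had an r across genes of 0.82 with Survivors of experiments 1 and 2. A swap with a sample outside the series was not tested.

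Other splits of the same arrays into groups of equal sizes were fitted in the same way. Of 100 splits for Survivors versus Control, drawn from 1716 possible, only the real one gave as many genes (3247, highest other 1897). The highest other split shared 5 of its 6 members with the real group, and the median of the other splits was 0. The real split also gave the most genes for Repeat versus Control (802, highest other 633, 1 of 100 drawn from 120 possible). That highest other split shared 2 of its 3 members with the real group, and the median of the other splits was 0. The real split gave the most genes as well for Reset versus Survivors (2763, highest other 1517, 1 of 84) and Repeat versus Survivors (2144, highest other 1111, 1 of 84). In both, the highest other split shared 0 members with the real group, and the median of the other splits was 0. Without Repeat replicate 1, Repeat versus Control gave 282, fewer than its highest other split. That count comes from a smaller group than the splits, so it is not set against them. The splits exchanged arrays between experiments, and few exchanges are possible within experiments, so they do not exclude chance. For Reset versus Control the real count is 0, so that 100 of 100 splits had to give at least as many, and the splits say nothing about chance. The split that set Control replicates 1 and 3 with Reset replicate 1, all of experiment 1, gave 1841. That points to a structure of the samples. Within experiment 2 Reset versus Control gave 0 genes (limma, 2 Reset arrays). In the pooled fit 257 genes had an unadjusted p under 0.05. Experiment 1 held 1 Reset array, too few for a count.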

How the results depend on the processing

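Settings chosen after seeing the data were the table as deposited, removal of experiment 1, experiment 3 alone, the crossed replicate block and the block for pairs by order. As reported, the counts were Survivors 3247, Reset 0, Repeat 802, Reset versus Survivors 2763, Repeat versus Survivors 2144, IKB_control 69, IKB_survivors 374, IETD_control 825, IETD_survivors 0, zVAD_control 37 and zVAD_survivors 0, and, for differences of TRAIL effects, IKB minus parental 27, IETD minus none 150, zVAD minus none 708 and IETD minus zVAD 3. Each setting lists only counts that moved by over 1.5 times; the cause was not tested except where the setting removes arrays. Of the 10 groups 6 hold 2 arrays each, replicates of experiment 1 spread most, and genes undetected in a group have no exact fold.

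The authors' normalized table gave zVAD_control 78 and IETD minus zVAD 20, and shared 3066 of the 3247 Survivors genes and 691 of the 802 Repeat genes. No background correction gave zVAD_control 59. No detection filter gave IKB minus parental 11, IETD minus none 76, zVAD_survivors 8 and IETD minus zVAD 31. An intensity trend moved no count past 1.5 times. No experiment term gave Survivors 1578, Repeat 274, Reset versus Survivors 1475, Repeat versus Survivors 1000, IKB_survivors 34, IKB minus parental 8, IETD minus none 9, zVAD minus none 41 and IETD minus zVAD 0, and turned RPL7 in IETD_control versus Control from -0.59 to 0.33.

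A replicate block in place of experiment gave Survivors 2039, Reset 6, Repeat versus Survivors 1333, IKB_control 11, IKB_survivors 26, IKB minus parental 6, IETD_control 0, IETD minus none 10, zVAD_control 0, zVAD minus none 25 and IETD minus zVAD 0, and with the IKB numbers crossed IKB_survivors had 29. In its comparisons of an inhibitor or IKB control with Control, this block leaves Control replicate 7 as the only Control array. Whether arrays were paired is not known; a block for pairs by order within experiment, run within each cell line and inhibitor, gave Reset 1, Repeat 469, IETD minus none 57, zVAD minus none 356 and IETD minus zVAD 1. Group by experiment as a random block (consensus correlation 0.18) gave Repeat 464, IKB_control 35, IKB_survivors 135, IKB minus parental 9, IETD_control 254, IETD minus none 19, zVAD_control 0, zVAD minus none 133 and IETD minus zVAD 0. Arrays averaged per group and experiment, with fewer values in the fit, gave Survivors 432, Repeat 46, Reset versus Survivors 635, Repeat versus Survivors 205, IKB_control 7, IKB_survivors 2, IKB minus parental 1, IETD_control 0, IETD minus none 1, zVAD_control 0, zVAD minus none 2 and IETD minus zVAD 0.

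Only the arrays of the compared groups gave Repeat 175, Repeat versus Survivors 1428, IKB_control 9, IKB_survivors 1165, IETD_control 9, IETD_survivors 3, zVAD_control 1 and zVAD_survivors 159. Only experiment 3 gave IKB minus parental 196, IETD minus none 998 and IETD minus zVAD 349. Experiment 3 alone gave IKB_control 377, IKB_survivors 1734, IETD_control 2309, IETD_survivors 30, zVAD_control 636 and zVAD_survivors 103, and an r of 0.184 between Survivors and zVAD_survivors. Without experiment 1 there were Reset 1, Repeat versus Survivors 3485, IKB_control 445, IKB minus parental 250, IETD_control 2241, IETD minus none 2053, zVAD_control 676 and zVAD minus none 2459. Without the Survivors arrays with conflicting texts there were IKB_control 34, IKB minus parental 8, IETD_control 497, IETD minus none 48, zVAD_control 0 and IETD minus zVAD 0; of the 2361 Survivors genes 2271 were among the 3247.

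The table as deposited, which joins different probes across experiments by construction, gave Survivors 1680, Repeat 464, Reset versus Survivors 1654, Repeat versus Survivors 1203, IKB_control 249, IKB_survivors 816, IKB minus parental 220, IETD_control 1506, IETD_survivors 5, IETD minus none 0, zVAD_control 483, zVAD_survivors 103, zVAD minus none 28 and IETD minus zVAD 241.

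With 1 array left out the ranges were Survivors 2665 to 3762, Reset 0 to 0, Repeat 282 to 1066, Reset versus Survivors 1549 to 2986, Repeat versus Survivors 1280 to 2375, IKB_control 23 to 93, IKB_survivors 17 to 79, IKB minus parental 5 to 74, IETD_control 133 to 1069, IETD_survivors 0 to 0, IETD minus none 8 to 445, zVAD_control 0 to 151, zVAD_survivors 0 to 0, zVAD minus none 34 to 1209 and IETD minus zVAD 0 to 49; where 1 array of a group remained, it was assumed to vary like the other groups.

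Of 117 list tests that passed, 7 passed with an estimated correlation, 109 with the authors' normalized table and 110 without the conflicting Survivors arrays. Over 7 settings the named genes kept their side of the threshold in 3968 cases, lost the call in 941 and gained it in 18. In 1 case the direction turned with a call in either fit. Any turn in direction without a call in either fit is counted among the 3968. With arrays averaged per group and experiment 430 cases lost the call and 287 were kept. Without an experiment term 245 lost it and 471 were kept. The reported adjusted p-values count arrays within an experiment as separate replicates, which the averaged setting does not. A block for the chip was not run, since the files used here do not give the chip.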

Other observations

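No test in this part was chosen after its result was seen except the fits of experiment 3 alone. Core histone genes went both ways in Survivors, with 9 of 19 higher, 5 lower and 5 not passed (9 and 5 adjusted over the list alone; median 0.31, at bounds 0.39; adjusted p = 0.0647). H2AC18 rose by 1.73 ± 0.23 on the log2 scale, H2BC5 by 1.20 ± 0.15 and the linker histone gene H1-2 by 1.15 ± 0.16. In the stress-response list HSPA5, a chaperone of the endoplasmic reticulum, rose by 0.75 ± 0.13, while PSAT1 (-0.79 ± 0.08) and ASNS (-0.72 ± 0.06), which make serine and asparagine, fell with PHGDH (7 higher, 5 lower and 9 not passed of 21; 9 and 6 adjusted over the list alone; median 0.05; adjusted p = 0.861).

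In experiment 3 alone SPRR2A, undetected in both inhibitor control groups, was higher with zVAD (at least 1.20-fold, adjusted p = 0.000343) and IETD (at least 1.29-fold, adjusted p = 0.0072), and SAA2, undetected in IETD control cells, with IETD (at least 1.17-fold, adjusted p = 0.0112). The changes with IETD and with zVAD had an r across genes of -0.35 (jackknife SE 0.331; simulated 0.00), from -0.46 without IETD_survivors replicate 2 to -0.08 without IETD_survivors replicate 1.

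The other lists in Survivors versus Control had the following values. The p53 target list had 3 higher, 3 lower and 12 not passed of 18 (3 and 3 adjusted over the list alone; median -0.09, test direction higher; adjusted p = 0.934), with TP53I3 1.07 ± 0.16 and CDKN1A 0.53 ± 0.12. Immediate early genes had 2 higher and 19 not passed of 21 (2 adjusted over the list alone; median 0.08; adjusted p = 0.369), heat shock proteins 2 higher, 2 lower and 12 not passed of 16 (2 and 2; median 0.01; adjusted p = 0.682), and glycolysis and hypoxia genes 7 higher, 2 lower and 15 not passed of 24 (7 and 2; median 0.05; adjusted p = 0.16), NDRG1 among them (0.97 ± 0.12). Oxidative phosphorylation genes had 9 of 27 lower and 18 not passed (9 adjusted over the list alone; median -0.10; adjusted p = 0.0265, and adjusted p = 0.628 with an estimated correlation), ribosomal protein genes 4 of 30 lower and 26 not passed (2; median -0.04, at bounds -0.03; adjusted p = 0.267), and proteasome genes 2 of 26 lower and 24 not passed (0 adjusted over the list alone in limma; median -0.04; adjusted p = 0.577). Luminal markers had 5 higher, 1 lower and 4 not passed of 10 (5 and 3; median 0.18; adjusted p = 0.2), MUC1 among them (1.57 ± 0.20), and mesenchymal genes 6 higher, 2 lower and 7 not passed of 15 (7 and 2; median 0.24; adjusted p = 0.164), with LOX 1.53 ± 0.19 and SPARC -0.73 ± 0.12. YAP/TEAD targets had 6 higher, 3 lower and 11 not passed of 20 (6 and 3; median 0.11, at bounds 0.08; adjusted p = 0.152), EGFR ligands and regulators 4 higher, 3 lower and 13 not passed of 20 (4 and 3; median 0.01, test direction lower; adjusted p = 0.987), and autophagy and lysosome genes 9 higher, 4 lower and 14 not passed of 27 (9 and 4; median 0.15; adjusted p = 0.0327, and adjusted p = 0.433 with an estimated correlation).

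Few markers of other cell types were measured. Fibroblast markers had 3 of 5 higher and 2 not passed in Survivors (3 adjusted over the list alone; median 1.13; adjusted p = 0.0271, and adjusted p = 0.309 with an estimated correlation), DCN (2.20 ± 0.47), FAP (1.70 ± 0.15) and MFAP5 (1.13 ± 0.18). Leukocyte markers had 1 of 4 higher and 3 not passed (3 adjusted over the list alone; median 0.33; adjusted p = 0.17), and endothelial markers 1 of 2 lower and 1 not passed (1 adjusted over the list alone; median -0.15; adjusted p = 0.606).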
